A study of Mus musculus with 15 samples.

How the data were processed

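RNA from B cells of AM-14 mice was measured on 15 Affymetrix mouse arrays, 1 array per sample. Per the labels, total RNA was extracted with Qiagen RNeasy columns and labelled with biotin, with the Enzo kit for replicates 1 and 2 of every group and the Ambion kit for replicate 3. The deposited values were probe set signals, a linear intensity from MAS5 according to the submitters' processing notes, which give no version or target value. After leaving out the lowest and highest 2% of probe sets, the mean signal was nearly equal on all 15 arrays, as scaling each array as a whole gives. The 64 control probe sets were kept out of the gene tests, and all 3 empty cells of the table belonged to them. The doses, the times of stimulation and the origin of the replicates were not given in the sources used here.

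The samples were grouped by the labels into 5 groups of 3: media, anti-IgM, CpG, PL2-3, and anti-IgM with CpG. For the last group the titles and descriptions name both agents while the treatment field reads none, and the titles were followed. Of 45037 probe sets, 34945 had 1 gene symbol, 932 several and 9160 none listed, and 34754 matched a gene of the RefSeq gene table by gene identifier. Probe sets with several symbols or none were left out. Each of 18193 genes was represented by its probe set with the highest mean signal, and the 13146 genes at or above the array median on at least 3 of the 15 arrays were tested. Signals were used as log2 of the signal plus 75.1, the 20th percentile of all signals. Computations used R 4.3.3 with limma 3.58.1 and jsonlite 2.0.0, and the figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

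One linear model with the 5 groups and the labelling kit as terms was fitted over all 15 arrays with limma lmFit, leaving 9 residual degrees of freedom, and tested with eBayes with an intensity trend. All p-values are two-sided. Adjusted p-values are Benjamini-Hochberg values within a comparison, and a gene was called at an adjusted p under 0.05. Each stimulated group was compared with media, PL2-3 with each other stimulated group, and anti-IgM, CpG and their combination with one another. Non-additivity was the log2 change with both agents minus the sum of the changes with each. With 3 arrays per group the smallest two-sided exact permutation p is 0.1, so no exact test could have passed the threshold, and the number of arrays limits the precision.

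The fit, the comparisons, the rule for naming genes and 25 gene lists were chosen before the data were examined. The lists were tested with camera at a preset correlation of 0.01 between genes, adjusted over the lists within a comparison, and again with the correlation estimated for each list. They held 464 distinct genes, of which 422 were tested, and a result of each list is printed in the report. Named genes were, for each comparison against media, the 8 largest rises and the 6 largest falls among called genes changed the same way in all 3 same-numbered pairs of arrays. For the other comparisons and for non-additivity they were the 5 largest in each direction under the same condition. Up to 4 called members of each list were named besides, a list without one was shown by its member with the highest signal, and list members were followed through other comparisons. Not every gene that the rule allows is printed. Of 39 gene-comparison pairs named by size with other probe sets passing the filter, 8 had a probe set that went the opposite way. Those 8 are not printed. They include Nr4a2 in CpG against anti-IgM (-4.41, other probe sets from -3.23 to 0.30). Mxd4 for non-additivity (3.29, other probe sets from -0.20 to 3.01) is among them too. Immunoglobulin segments were not named.

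To test the procedure, 200 of 13146 simulated genes were changed. Of genes changed 4-fold, 74.2% to 89.4% were called in comparisons of 2 groups and 59.1% for non-additivity. Of 2-fold ones, 22.4% to 43.3% and 11.9% were. Unchanged genes gave 0 to 7 calls per comparison. A list with a planted shift was called and 0 of 24 others, which does not cover lists of correlated genes.

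Whether the replicate numbers pair the arrays was checked on each array's deviations from its group mean. Without anti-IgM+CpG, all 18 same-numbered pairs correlated above 0.1 across genes, against 13 of 60 pairs with different numbers. Same-numbered pairs with an anti-IgM+CpG array gave 0 of 12, so naming there paired by number only. The kit follows the numbers in part, and they were tried as a block.

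The alternatives planned were quantile normalization, arrays shifted to the same median, no pseudocount or a pseudocount of 245 (the 40th percentile), no filter or a filter on all 15 arrays, and no labelling term or a replicate block. They also covered the Enzo arrays only, eBayes without a trend, a fit of the compared groups only, the mean of a gene's probe sets, a 2-fold minimum and leaving out each array. After the data were seen, a labelling term read from the beta-actin control probe sets was added, called actin-based, with arrays under a 5' to 3' ratio of 0.260 taken as Ambion-like. A fit without the anti-IgM+CpG arrays, a fit of the 7 Ambion-like arrays, and gene lists with arrays shifted to the same median and with 1 array left out were added then too.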

Results

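Gene expression was measured on Affymetrix mouse arrays in B cells of AM-14 mice, whose transgenic B cell receptor binds self IgG. The 15 arrays fell into 5 groups of 3: cells kept in media, and cells stimulated with anti-IgM antibody fragments, with the CpG oligodeoxynucleotide 1826, with PL2-3, or with anti-IgM and CpG together. Anti-IgM crosslinks the B cell receptor and CpG engages TLR9. PL2-3 is an antibody to chromatin, and the labels describe its treatment as chromatin immune complexes, which bring DNA into AM-14 cells through the receptor. Each array held 45037 probe sets besides the controls, the array medians lay between 263 and 514 signal units, and 13146 genes were tested. Changes are given as log2 values ± SE from limma with n = 3 arrays per group, and a gene is said to have risen or fallen where its limma adjusted p was under 0.05. The genes named for the size of their change moved the same way in all 3 same-numbered pairs of arrays. No label says whether the 3 arrays of a group came from separate cultures or animals, so the p-values measure the spread between arrays, and the number of arrays limits the precision.

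The anti-IgM+CpG arrays stood apart from the other 12 in measured ways that bear on each comparison that uses them. Xist, the RNA made from the inactive X chromosome of female cells, had signals of 321 to 589 on these 3 arrays and of 4252 to 15543 on the other 12. The labels name the Enzo labelling kit for replicates 1 and 2 of every group and the Ambion kit for replicate 3. In the other 4 groups the ratio of the 5' to the 3' control probe sets for beta-actin was 0.335 to 0.747 on the 8 Enzo arrays and 0.108 to 0.201 on the 4 Ambion arrays. On the 3 anti-IgM+CpG arrays it was 0.105 to 0.193. Values from a fit with the labelling read from these ratios are therefore printed beside those from the kits as the labels give them, and are called actin-based.

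**Figure D1:**
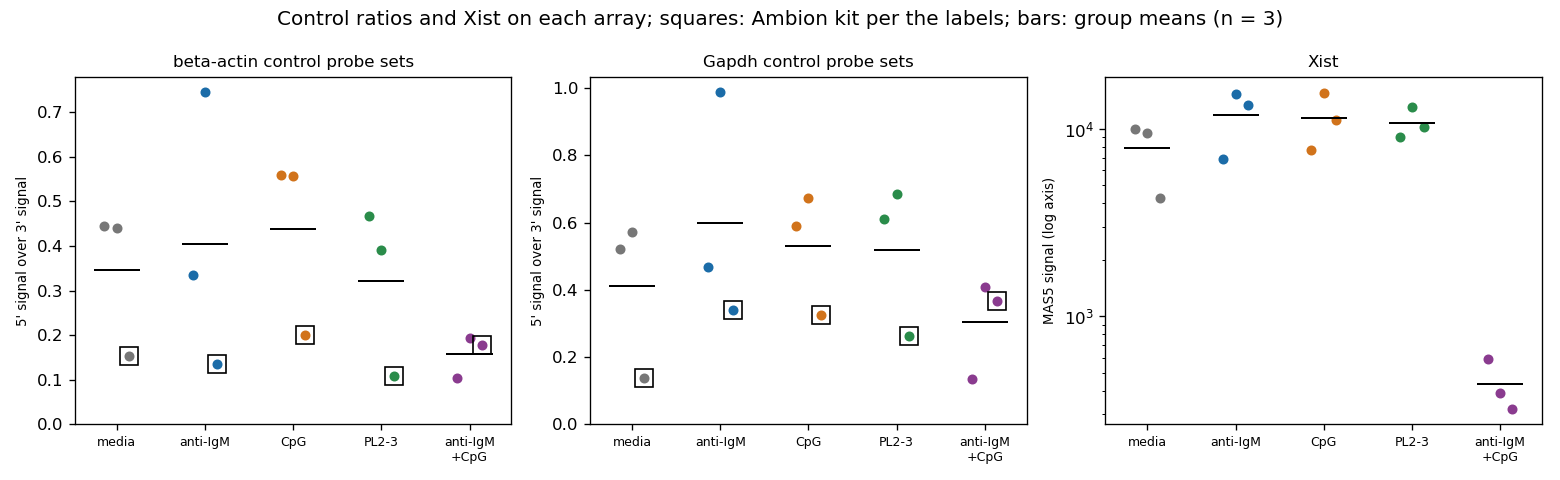
The 5' to 3' signal ratio of the beta-actin and Gapdh control probe sets (linear axes) and the MAS5 signal of Xist (log axis) on each of the 15 arrays, with squares around arrays labelled with the Ambion kit per the labels and bars at the group means (n = 3). The actin ratios of the anti-IgM+CpG arrays lie between 0.105 and 0.193 and their Xist signals between 321 and 589, under the 4252 to 15543 of the other arrays.

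Stimulation through the B cell receptor alone, anti-IgM against media, raised the chemokine Xcl1 by 4.37 ± 0.32 log2 units (n = 3 arrays per group), from a mean signal of 595 ± 121 to 13639 ± 1698 (SD). Bex1 rose by 3.98 ± 0.34, the calcium sensor Ncs1 by 3.02 ± 0.38 and Mir155hg, the host transcript of a microRNA made in activated lymphocytes, by 2.79 ± 0.46. Ahr, a ligand-activated transcription factor, rose by 3.13 ± 0.29 on its brightest probe set, and another that passed the filter gave 0.35. The tryptophan pathway enzyme Haao changed by -3.43 ± 0.66, the guanine exchange factors Arhgef18 and Rasgrp2 by -3.19 ± 0.30 and -3.04 ± 0.33, and the surface protein Cd7 by -3.13 ± 0.53. Among immediate early genes, the transcription factors Egr2 (2.31 ± 0.22), Nr4a3 (2.27 ± 0.38), Nr4a2 (2.24 ± 0.31) and Myc (2.15 ± 0.24) rose. In this list, 11 of 20 tested members rose, 2 fell and 7 were not called (11 rose and 3 fell adjusted over the list alone). The immediate early list had a median log2 change of 0.71 (camera adjusted p = 0.000173, and 0.282 with an estimated correlation). Interferon-stimulated genes included Mx2 (1.96 ± 0.37) and Bst2 (1.78 ± 0.33), restriction factors against viruses. In this list, 8 of 27 tested members rose and 19 were not called (8 adjusted over the list alone). Interferon-stimulated genes had a median change of 0.72 (camera adjusted p = 0.000109, and 0.383 with an estimated correlation). Of the cytokines and chemokines, Ccl3 (2.52 ± 0.31) and Ccl4 (2.03 ± 0.29) rose and Ltb (-2.79 ± 0.47), which encodes lymphotoxin beta, fell, but the list as a whole was not called (camera adjusted p = 0.185, and 0.349 with an estimated correlation).

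Genes for making ribosomes moved together with anti-IgM. The RNA polymerase I subunit Polr1b rose by 2.05 ± 0.23, the rRNA processing factors Rrp9 and Rrp12 by 2.02 ± 0.21 and 1.85 ± 0.21, and the nucleolar protein Nolc1 by 1.81 ± 0.24. For ribosome biogenesis, 22 of 23 tested members rose and 1 was not called (23 adjusted over the list alone). Ribosome biogenesis genes had a median change of 1.26 (camera adjusted p = 2.35e-23, and 0.0585 with an estimated correlation). In glycolysis and lactate export, Pfkp (1.67 ± 0.18), a phosphofructokinase, Hk2 (1.43 ± 0.14), a hexokinase, and Slc16a1 (1.18 ± 0.21), a lactate transporter, rose. In this list, 8 of 14 tested members rose and 6 were not called (9 rose and 1 fell adjusted over the list alone). The glycolysis list had a median of 0.62 (camera adjusted p = 2.38e-05, and 0.0585 with an estimated correlation). Cholesterol genes rose too, among them Sqle (1.90 ± 0.18), which encodes squalene epoxidase, Idi1 (1.26 ± 0.19) and Cyp51 (1.24 ± 0.19). In this list, 12 of 17 tested members rose and 5 were not called (13 adjusted over the list alone). Cholesterol genes had a median change of 0.84 (camera adjusted p = 1.22e-08, and 0.0518 with an estimated correlation). The chaperones Hsph1 (1.36 ± 0.17) and Hspd1 (1.12 ± 0.14) rose. Of the heat shock and stress genes 4 of 12 tested members rose, 1 fell and 7 were not called (4 rose and 1 fell adjusted over the list alone). Heat shock genes had a median change of 0.43 (camera adjusted p = 0.00171, and 0.0518 with an estimated correlation). Surface molecules of activation were mixed, with Il2ra (1.48 ± 0.32) and Cd86 (1.38 ± 0.27) higher and Icosl (-2.05 ± 0.31) lower, and this list was not called (camera adjusted p = 0.185, and 0.477 with an estimated correlation).

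Genes of the resting B cell fell with anti-IgM. Ypel3 (-2.24 ± 0.26), the lymphocyte transcription factor Ets1 (-2.05 ± 0.35) and the retinoblastoma relative Rbl2 (-1.93 ± 0.22) fell. In this list, 12 of 20 tested members fell and 8 were not called (12 adjusted over the list alone). Quiescence genes had a median change of -0.93 (camera adjusted p = 5.08e-07, and 0.0518 with an estimated correlation). The receptor's own signalling chains Cd79b (-2.28 ± 0.37) and Cd79a (-1.84 ± 0.27) fell, as did the inhibitory receptors Cd22 (-2.21 ± 0.35) and Fcgr2b (-2.18 ± 0.32). For BCR signalling, 12 of 22 tested members fell and 10 were not called (2 rose and 14 fell adjusted over the list alone). BCR signalling genes had a median change of -0.83 (camera adjusted p = 4.00e-05, and 0.218 with an estimated correlation). For the B cell lineage list, 11 of 13 tested members fell and 2 were not called (11 adjusted over the list alone). B lineage genes had a median change of -1.55 (camera adjusted p = 1.50e-08, and 0.0585 with an estimated correlation). Of the myeloid markers, 8 of 20 tested members fell and 12 were not called (9 adjusted over the list alone). Myeloid markers had a median change of -1.0 (camera adjusted p = 0.000396, and 0.364 with an estimated correlation), and of -0.60 without media replicate 3. NK cell and erythroid markers were called lower, at medians of -0.81 and -1.08 (camera adjusted p = 0.0199, and 0.383 with an estimated correlation, and camera adjusted p = 0.0248, and 0.383 with an estimated correlation), and T cell markers were not called (camera adjusted p = 0.117, and 0.413 with an estimated correlation). The NK cell call ended without media replicate 3 (0.0812) or anti-IgM replicate 2 (0.0635). The erythroid call ended without media replicate 3, at a median of -0.53 (0.154). By limma at an adjusted p of 0.05, 2561 genes changed with anti-IgM, 1337 up and 1224 down, and 15 of 25 lists were called by camera. With an estimated correlation camera called 0 lists, with 6 at an unadjusted p under 0.05, and 6 with actin-based labelling, among them cholesterol (0.0293), quiescence (0.0440) and immediate early genes (0.0440). The share of higher genes among those called was 52.2% with the deposited scaling and 79.5% with arrays shifted to the same median, and the median change of all genes went from -0.12 to 0.14. Without media replicate 3 the count was 1654, without anti-IgM replicate 3 it was 1672, and with the Enzo arrays only it was 1438.

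Stimulation through TLR9 alone, CpG against media, raised Il6 by 4.85 ± 0.33 log2 units (n = 3 arrays per group). Ifng, which encodes interferon gamma, rose by 5.56 ± 0.76, but its media signals of 14.2 to 31.2 lay under the pseudocount, and the size of its rise went from 4.18 with a pseudocount of 245 to 7.67 with none. Ebi3, a subunit of interleukin 27, rose by 3.49 ± 0.23, the interferon-induced chemokine Cxcl10 by 3.48 ± 0.50, and Il12b, a subunit of interleukin 12, by 3.09 ± 0.43. The small GTPase Rnd3 rose by 3.92 ± 0.55 and the nuclear lamin Lmnb2 by 3.67 ± 0.24. The B cell protein Fcrla changed by -4.26 ± 0.34, the Myc antagonist Mxd4 by -3.95 ± 0.58, the small GTPase Rab30 by -4.01 ± 0.52 and Haao by -4.09 ± 0.66. The mean signal of Rab30 with CpG also lay under the pseudocount, and its change went from -2.94 with a pseudocount of 245 to -5.25 with none. For cytokines and chemokines, 10 of 22 tested members rose, 2 fell and 10 were not called (12 rose and 2 fell adjusted over the list alone). Cytokines and chemokines had a median change of 0.86 (camera adjusted p = 2.42e-05, and 0.0177 with an estimated correlation). The NF-kB targets Nfkbiz (3.32 ± 0.20), which encodes a nuclear IkB protein, Cflar (2.12 ± 0.23), an inhibitor of caspase activation, and Cd40 (2.04 ± 0.28) rose. In this list, 8 of 16 tested members rose and 8 were not called (8 adjusted over the list alone). NF-kB targets had a median change of 0.71 (camera adjusted p = 6.79e-07, and 0.0886 with an estimated correlation). Interferon-stimulated genes rose as well, with Mx2 at 3.64 ± 0.37, Bst2 at 2.41 ± 0.33 and Mx1 at 1.99 ± 0.34. In this list, 16 of 27 tested members rose and 11 were not called (16 adjusted over the list alone). Interferon-stimulated genes had a median change of 1.09 (camera adjusted p = 1.61e-08, and 0.293 with an estimated correlation). The immediate early genes split: Jun (3.34 ± 0.26) and Myc (2.13 ± 0.24) rose while Egr3 (-2.96 ± 0.26) and Nr4a2 (-2.18 ± 0.31) fell, and the list was not called (camera adjusted p = 0.0813, and 0.502 with an estimated correlation).

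In ribosome biogenesis, all 23 tested members rose (23 adjusted over the list alone). Ribosome biogenesis genes had a median change of 1.55 (camera adjusted p = 8.12e-22, and 0.0886 with an estimated correlation), led by Rrp9 (2.34 ± 0.21), Polr1b (2.31 ± 0.23) and Nop16 (2.01 ± 0.19). Cholesterol synthesis and uptake had a median of 0.32 (camera adjusted p = 0.000278, and 0.151 with an estimated correlation), and of 0.53 without media replicate 3. In this list, 6 of 17 tested members rose and 11 were not called (6 adjusted over the list alone), among them Sqle (1.43 ± 0.18) and Fdps (1.23 ± 0.17). The cyclin gene Ccnd2 rose by 2.55 ± 0.26 and the kinase gene Cdk6 by 1.80 ± 0.28. The list of G1-S and DNA replication genes was not called, with a median of -0.19, a mean of -0.09 and a test that leaned higher (camera adjusted p = 0.468, and 0.799 with an estimated correlation). Socs1 (2.74 ± 0.35) and Socs3 (2.16 ± 0.21), feedback inhibitors of cytokine signalling, rose, and so did Tlr7 (1.43 ± 0.26). The TLR signalling list was not called, with a median of -0.23, a mean of 0.12 and a test that leaned higher (camera adjusted p = 0.468, and 0.502 with an estimated correlation). Batf, an AP-1 family transcription factor needed for class switching, rose by 2.79 ± 0.24 and the B cell coactivator Pou2af1 changed by -2.60 ± 0.17. The class switching and germinal centre list was not called, with a median of -0.02, a mean of 0.10 and a test that leaned higher (camera adjusted p = 0.372, and 0.502 with an estimated correlation). Of the apoptosis regulators, the survival genes Pim2 (1.69 ± 0.26) and Bcl2 (1.49 ± 0.24) rose. In this list, 5 of 17 tested members rose, 5 fell and 7 were not called (5 rose and 6 fell adjusted over the list alone). Apoptosis regulators had a median change of -0.21 (camera adjusted p = 0.946, and 0.977 with an estimated correlation). For plasma cell differentiation, 2 of 11 tested members rose, 4 fell and 5 were not called (2 rose and 5 fell adjusted over the list alone). Plasma cell genes had a median change of -0.88 (camera adjusted p = 0.318, and 0.598 with an estimated correlation). For the unfolded protein response, 2 of 18 tested members rose, 3 fell and 13 were not called (2 rose and 3 fell adjusted over the list alone). Unfolded protein response genes had a median change of -0.21 (camera adjusted p = 0.946, and 0.977 with an estimated correlation).

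The quiescence list fell with CpG, with Ypel3 at -2.43 ± 0.26, the cell cycle inhibitor Cdkn1b at -2.25 ± 0.37 and Ccr6, a chemokine receptor, at -2.90 ± 0.33. In this list, 15 of 20 tested members fell and 5 were not called (1 rose and 18 fell adjusted over the list alone). Quiescence genes had a median change of -1.46 (camera adjusted p = 6.79e-07, and 0.0448 with an estimated correlation). In BCR signalling, the phosphatase Inpp5d (-2.92 ± 0.20), Fcgr2b (-2.45 ± 0.32) and Cd22 (-2.02 ± 0.35) fell. In this list, 1 of 22 tested members rose, 14 fell and 7 were not called (1 rose and 15 fell adjusted over the list alone). BCR signalling genes had a median change of -0.88 (camera adjusted p = 0.000134, and 0.216 with an estimated correlation). For the B cell lineage list, 9 of 13 tested members fell and 4 were not called (9 adjusted over the list alone), with Fcmr, the receptor for the Fc part of IgM, at -2.75 ± 0.26. B lineage genes had a median change of -1.74 (camera adjusted p = 0.000135, and 0.215 with an estimated correlation). Marginal zone markers fell, with the sphingosine receptor S1pr3 at -2.25 ± 0.21 and the complement receptor Cr2 at -1.52 ± 0.20. In this list, 7 of 9 tested members fell and 2 were not called (9 adjusted over the list alone). Marginal zone markers had a median change of -1.15 (camera adjusted p = 0.000134, and 0.0886 with an estimated correlation). Myeloid, T cell and erythroid markers were called lower, at medians of -0.80, -0.85 and -1.49, with camera adjusted p of 0.00329, 0.0293 and 0.0328, and of 0.461, 0.397 and 0.475 with an estimated correlation. NK cell markers were not called (camera adjusted p = 0.0728, and 0.502 with an estimated correlation). Without media replicate 3 the T cell and erythroid calls ended, at medians of -0.55 (0.0603) and -0.76 (0.0980). The T cell call also ended without CpG replicate 2 (0.0766) and after quantile normalization (0.0515), and the erythroid call without CpG replicate 3 (0.0678). Without media replicate 1 the T cell median was -1.38. By limma, 3975 genes changed with CpG, 1742 up and 2233 down, with 17 of 25 lists called and 2 of them, cytokines and quiescence, held with an estimated correlation, quiescence not with actin-based labelling (0.0747). Higher genes were 43.8% of those called, 50.9% after quantile normalization and 77.9% with arrays shifted to the same median, where the median change of all genes went from -0.21 to 0.18. With the Enzo arrays only, 2481 genes were called.

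Chromatin complexes, PL2-3 against media, ask what stimulation through both receptors by 1 ligand does. Xcl1 rose by 5.06 ± 0.32 log2 units (n = 3 arrays per group), from a mean signal of 595 ± 121 to 22237 ± 4407 (SD). Crabp2, a retinoic acid binding protein, rose by 3.69 ± 0.47, the protease inhibitors Cst7 and Serpinb9b by 3.58 ± 0.20 and 3.38 ± 0.33, Bcat1, an enzyme of amino acid breakdown, by 3.28 ± 0.20, and the chemokine Ccl3 by 3.34 ± 0.31. Ifng rose by 3.60 ± 0.76, with signals of 4076, 3618 and 34.6 on the PL2-3 arrays and of 14.2 to 31.2 on the media arrays, under the pseudocount, so that its rise went from 2.64 with a pseudocount of 245 to 5.16 with none. Mxd4 changed by -3.67 ± 0.58, Arhgef18 by -3.57 ± 0.30, Haao by -3.46 ± 0.66 and the cannabinoid receptor Cnr2 by -3.32 ± 0.38. Among cytokines and chemokines, Il6 (3.21 ± 0.33) and Ccl4 (2.72 ± 0.29) rose and Ltb (-2.80 ± 0.47) fell. In this list, 6 of 22 tested members rose, 3 fell and 13 were not called (6 rose and 3 fell adjusted over the list alone). Cytokines and chemokines had a median change of 0.25 (camera adjusted p = 0.0347, and 0.113 with an estimated correlation). Without media replicate 3 this median was 0.44. Without PL2-3 replicate 2 the camera adjusted p of the cytokine list was 0.0648. Interferon-stimulated genes went the other way from CpG, with Ifit3 at -2.43 ± 0.51. In this list, 1 of 27 tested members rose, 11 fell and 15 were not called (1 rose and 11 fell adjusted over the list alone). Interferon-stimulated genes had a median change of -0.70 (camera adjusted p = 0.00639, and 0.520 with an estimated correlation). Egr2 (2.15 ± 0.22), Nr4a3 (2.34 ± 0.38) and Myc (2.10 ± 0.24) rose, with the immediate early list not called (camera adjusted p = 0.0945, and 0.520 with an estimated correlation).

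Ribosome biogenesis with PL2-3 included Rrp9 at 2.37 ± 0.21, Polr1b at 2.17 ± 0.23 and Nolc1 at 1.91 ± 0.24. In this list, all 23 tested members rose (23 adjusted over the list alone). Ribosome biogenesis genes had a median change of 1.49 (camera adjusted p = 5.67e-21, and 0.0791 with an estimated correlation). Hk2 (1.97 ± 0.14), Slc16a1 (1.47 ± 0.21) and the glycolytic enzyme Pgam1 (1.05 ± 0.17) rose. For glycolysis and lactate export, 8 of 14 tested members rose, 1 fell and 5 were not called (8 rose and 1 fell adjusted over the list alone). Glycolysis genes had a median change of 0.74 (camera adjusted p = 0.000303, and 0.113 with an estimated correlation). For cholesterol synthesis and uptake, 13 of 17 tested members rose and 4 were not called (14 adjusted over the list alone), with Sqle at 1.74 ± 0.18. Cholesterol genes had a median change of 0.92 (camera adjusted p = 8.03e-09, and 0.0623 with an estimated correlation). The G1-S and DNA replication list was not called (camera adjusted p = 0.399, and 0.716 with an estimated correlation), with Ccnd2 at 1.62 ± 0.26, the kinase Cdk4 at 1.27 ± 0.15 and the cyclin Ccne2 at -1.76 ± 0.27. Mitosis genes fell, with the centromere protein Cenpa at -1.85 ± 0.33. In this list, 12 of 23 tested members fell and 11 were not called (17 adjusted over the list alone). Mitosis genes had a median change of -1.34 (camera adjusted p = 0.000190, and 0.430 with an estimated correlation), and of -0.80 without media replicate 3. On that array the mitosis gene Cdc20 had a signal of 21972, against 5511 and 3596 on the other media arrays. Gadd45b (1.44 ± 0.29) rose and its relative Gadd45a (-1.96 ± 0.39) fell among the stress genes, where 5 of 12 tested members rose, 1 fell and 6 were not called (5 rose and 1 fell adjusted over the list alone). Heat shock genes had a median change of 0.47 (camera adjusted p = 0.00939, and 0.0791 with an estimated correlation).

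Quiescence genes fell with PL2-3, led by Ets1 (-2.94 ± 0.35), Ypel3 (-2.39 ± 0.26) and Rbl2 (-1.80 ± 0.22). In this list, 15 of 20 tested members fell and 5 were not called (18 adjusted over the list alone). Quiescence genes had a median change of -1.29 (camera adjusted p = 4.69e-09, and 0.0319 with an estimated correlation). The adaptor Bank1 (-2.74 ± 0.28), Cd22 (-2.61 ± 0.35) and Cd79b (-2.49 ± 0.37) fell. For BCR signalling, 1 of 22 tested members rose, 12 fell and 9 were not called (2 rose and 12 fell adjusted over the list alone). BCR signalling genes had a median change of -0.83 (camera adjusted p = 1.42e-05, and 0.146 with an estimated correlation). Of the B cell lineage list, 12 of 13 tested members fell and 1 was not called (13 adjusted over the list alone). B lineage genes had a median change of -1.84 (camera adjusted p = 5.50e-09, and 0.0791 with an estimated correlation). For antigen presentation, 7 of 19 tested members fell and 12 were not called (7 adjusted over the list alone), with H2-Ob (-2.19 ± 0.25) and H2-Oa (-1.94 ± 0.24), which modulate peptide loading, lower. Antigen presentation genes had a median change of -0.40 (camera adjusted p = 0.00374, and 0.423 with an estimated correlation), and of -0.22 without PL2-3 replicate 2. Of the marginal zone markers, 5 of 9 tested members fell and 4 were not called (6 adjusted over the list alone). Marginal zone markers had a median change of -1.0 (camera adjusted p = 0.00378, and 0.146 with an estimated correlation). Of the erythroid markers, all 5 tested members fell (5 adjusted over the list alone), with the anion exchanger Slc4a1 at -1.66 ± 0.38 (camera adjusted p = 0.00672, and 0.363 with an estimated correlation). Of the myeloid markers, 6 of 20 tested members fell and 14 were not called (11 adjusted over the list alone), with the lysozyme gene Lyz2 at -1.79 ± 0.41 (camera adjusted p = 0.000303, and 0.362 with an estimated correlation). By limma, 3426 genes changed with PL2-3, 1642 up and 1784 down, with 15 of 25 lists called and 1, quiescence, held with an estimated correlation, to which actin-based labelling added cholesterol (0.0279). Higher genes were 47.9% of those called and 67.3% with arrays shifted to the same median, where the median change of all genes went from -0.09 to 0.11.

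With anti-IgM and CpG together, against media, Ifng rose by 6.0 ± 0.76 log2 units (actin-based 7.40 ± 0.90, n = 3 arrays per group) and Xcl1 by 4.44 ± 0.32 (4.67 ± 0.34). Tbx21, which encodes the transcription factor T-bet, rose by 4.02 ± 0.47 (4.21 ± 0.53), Ccl3 by 3.61 ± 0.31 (4.30 ± 0.31), and Arc, an immediate early gene of neurons, by 3.53 ± 0.63 (2.43 ± 0.67). The mean media signals of Ifng and Arc lay under the pseudocount, and the rises went from 4.60 with a pseudocount of 245 to 8.11 with none for Ifng and from 2.50 with a pseudocount of 245 to 4.69 with none for Arc. Haao changed by -5.06 ± 0.66 (-5.65 ± 0.73), Cnr2 by -4.98 ± 0.38 (-4.74 ± 0.44), the kinase Stk10 by -4.43 ± 0.47 (-4.18 ± 0.52) and the ceramide kinase Cerk by -4.14 ± 0.30 (-4.05 ± 0.34). Il6 (3.34 ± 0.33, actin-based 3.87 ± 0.36) and Cxcl10 (2.88 ± 0.50, 3.26 ± 0.59) rose. Of the cytokines and chemokines, 12 of 22 tested members rose, 2 fell and 8 were not called (12 rose and 2 fell adjusted over the list alone). Their median change was 0.94 and 0.91 actin-based (camera adjusted p = 0.000324, and 0.0295 with an estimated correlation). Nfkbiz (2.61 ± 0.20, actin-based 3.06 ± 0.21) and Icam1 (1.68 ± 0.19, 1.35 ± 0.19), an adhesion molecule, rose among NF-kB targets. In that list, 10 of 16 tested members rose, 2 fell and 4 were not called (10 rose and 2 fell adjusted over the list alone). Their median change was 0.88 and 1.0 actin-based (camera adjusted p = 0.000211, and 0.172 with an estimated correlation). Mx2 rose by 2.90 ± 0.37 (actin-based 3.08 ± 0.40) and Ifih1, a sensor of viral RNA, by 2.18 ± 0.33 (2.11 ± 0.36). For interferon-stimulated genes, 13 of 27 tested members rose and 14 were not called (13 adjusted over the list alone). Their median change was 0.93 and 1.03 actin-based (camera adjusted p = 6.49e-06, and 0.412 with an estimated correlation), and 0.36 without anti-IgM+CpG replicate 1. Batf rose by 2.90 ± 0.24 (actin-based 2.96 ± 0.26).

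In ribosome biogenesis, all 23 tested members rose (23 adjusted over the list alone), with Rrp9 at 2.99 ± 0.21 (actin-based 2.71 ± 0.23). Ribosome biogenesis genes had a median change of 1.83 and 1.69 actin-based (camera adjusted p = 1.94e-19, and 0.0905 with an estimated correlation). For cholesterol synthesis and uptake, 13 of 17 tested members rose and 4 were not called (14 adjusted over the list alone), with Sqle at 2.15 ± 0.18 (actin-based 1.78 ± 0.19). Cholesterol genes had a median change of 1.04 and 0.78 actin-based (camera adjusted p = 5.72e-09, and 0.0356 with an estimated correlation). Hk2 (2.47 ± 0.14, actin-based 2.55 ± 0.15) rose. For glycolysis and lactate export, 10 of 14 tested members rose, 3 fell and 1 were not called (10 rose and 3 fell adjusted over the list alone). Glycolysis genes had a median change of 0.86 (camera adjusted p = 0.000187, and 0.0905 with an estimated correlation). In quiescence, Ets1 (-3.93 ± 0.35, actin-based -4.01 ± 0.38) and Klf2 (-3.24 ± 0.33, -2.79 ± 0.33), a factor of resting lymphocytes, fell. In this list, 18 of 20 tested members fell and 2 were not called (19 adjusted over the list alone). Quiescence genes had a median change of -1.87 and -1.63 actin-based (camera adjusted p = 7.19e-08, and 0.0295 with an estimated correlation). Cd79b (-3.63 ± 0.37, actin-based -4.03 ± 0.39) and Bank1 (-3.47 ± 0.28, -3.76 ± 0.27) fell. For BCR signalling, 1 of 22 tested members rose, 13 fell and 8 were not called (1 rose and 14 fell adjusted over the list alone). BCR signalling genes had a median change of -1.36 and -0.89 actin-based (camera adjusted p = 8.15e-05, and 0.178 with an estimated correlation). In the B cell lineage list, all 13 tested members fell (13 adjusted over the list alone). B lineage genes had a median change of -2.02 and -2.02 actin-based (camera adjusted p = 3.01e-07, and 0.0905 with an estimated correlation). Of the apoptosis regulators, the death-promoting Bcl2l11 (-2.41 ± 0.37, actin-based -1.05 ± 0.18) and Bmf (-2.21 ± 0.33, -2.57 ± 0.36) fell, with the list not called (camera adjusted p = 0.291, and 0.466 with an estimated correlation).

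Myeloid markers were lower with both agents, among them the complement gene C1qa (-3.74 ± 0.41, actin-based -2.32 ± 0.34) and the macrophage receptor Csf1r (-3.21 ± 0.32, -2.54 ± 0.28). In that list, 16 of 20 tested members fell and 4 were not called (16 adjusted over the list alone). Their median change was -1.53 and -1.29 actin-based (camera adjusted p = 4.21e-05, and 0.292 with an estimated correlation). T cell, NK cell and erythroid markers had medians of -1.21, -0.92 and -1.31. Their camera adjusted p was 0.0392, 0.0839 and 0.0797, and 0.412, 0.595 and 0.546 with an estimated correlation. The T cell call ended without media replicate 2 (0.0522) or 3 (0.0837) or anti-IgM+CpG replicate 2 (0.0902) or 3 (0.0516). Actin-based, the medians were -0.93, -0.44 and -1.09 and the adjusted p 0.117, 0.683 and 0.127. These values stand beside the low Xist and the Ambion pattern of the same 3 arrays. By limma, 5491 genes changed, 2258 up and 3233 down, and 4316 actin-based, 1873 up and 2443 down, with 3841 called the same way in both. Of 25 lists 14 were called, and cytokines, quiescence and cholesterol held with an estimated correlation. Actin-based, camera called 15, gaining immediate early (0.0300), activation (0.00385) and heat shock genes (0.0170) and losing T cells and the unfolded protein response (0.0595). Higher genes were 41.1% of those called, 54.7% after quantile normalization and 82.8% with arrays shifted to the same median, where the median change of all genes went from -0.28 to 0.36. From only the 7 arrays with the Ambion pattern, 2284 genes were called.

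**Figure D2:**
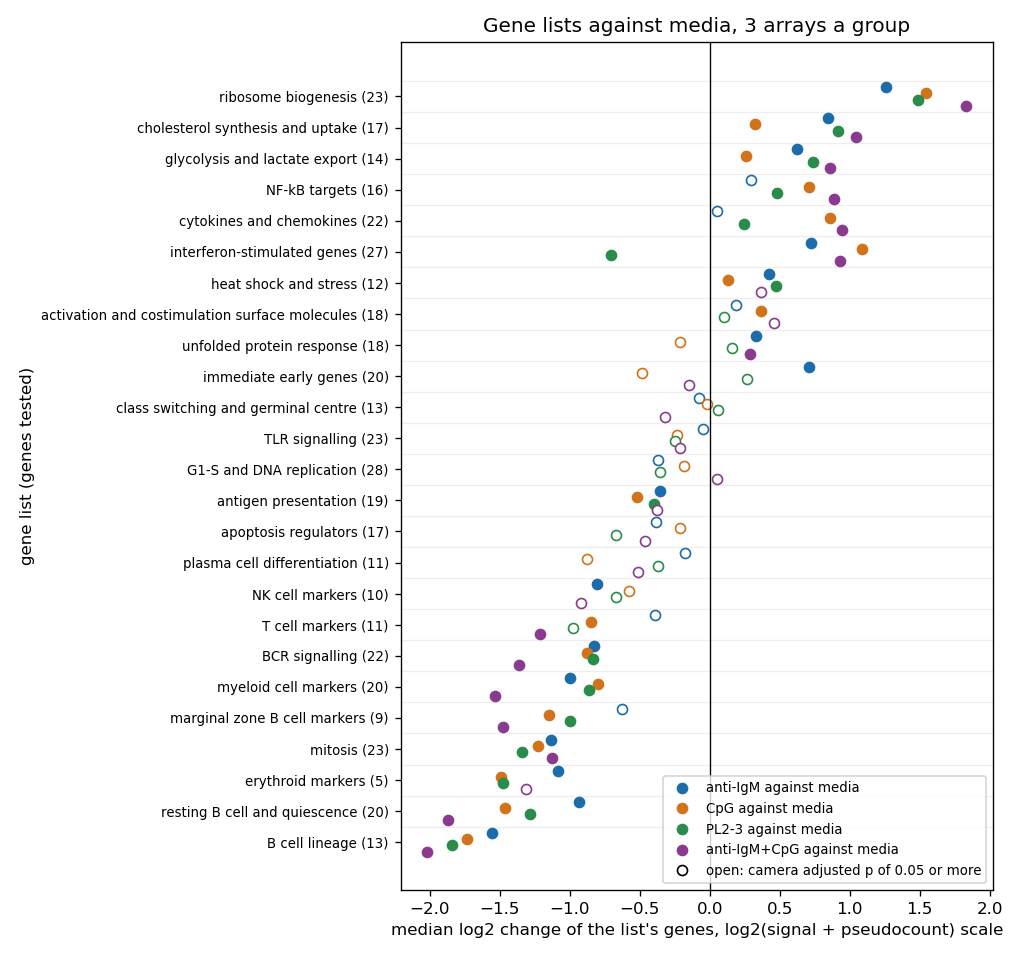
Median log2 change against media (horizontal axis) of the tested genes of each of 25 lists (vertical axis, number of genes tested in brackets) for the 4 stimulations, n = 3 arrays per group. Filled points have a camera adjusted p under 0.05 with the preset correlation, and the ribosome biogenesis points lie between 1.26 and 1.83.

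The 4 comparisons against media changed many of the same genes. In all 4, 997 genes rose and 798 fell, and of the 1642 genes that rose with PL2-3, 1499 also rose with anti-IgM or CpG and 143 with neither alone. Of the 1784 that fell with PL2-3, 1484 also fell with anti-IgM or CpG and 300 with neither. Ribosome biogenesis had medians of 1.26, 1.55, 1.49 and 1.83 with anti-IgM, CpG, PL2-3 and both, and the B cell lineage list of -1.55, -1.74, -1.84 and -2.02. Across genes, which are not independent replicates, the changes correlated at 0.846 for anti-IgM and PL2-3, 0.797 for CpG and PL2-3, 0.728 for anti-IgM and CpG, 0.791 for anti-IgM and both, 0.826 for CpG and both and 0.816 for PL2-3 and both. With the Enzo arrays only, anti-IgM and both correlated at 0.655 and PL2-3 and both at 0.667, where the arrays with both agents had Ambion-like actin ratios. All comparisons share the 3 media arrays, and 100 simulations of unchanged groups against shared controls gave correlations of 0.497 to 0.501 from that alone. The covariances were 0.366 to 0.595 against 0.0641 to 0.0644 in the simulations. Anti-IgM and PL2-3 shared 1180 genes higher and 999 lower, against 167 and 166 for independent calls, and CpG and PL2-3 shared 1329 and 1298 against 218 and 303. Anti-IgM and CpG shared 1049 and 904 against 177 and 208, and called 61 genes in opposite directions. Part of the excess can come from the shared media arrays, which cannot be divided so that each comparison keeps 2 or more of its own.

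PL2-3 against anti-IgM compares chromatin complexes with the receptor stimulus alone. Il6 was higher with PL2-3 by 3.31 ± 0.33 log2 units (n = 3 arrays per group), at a mean signal of 4872 ± 1480.0 against 451 ± 278 (SD). Serpinb9b was higher by 3.11 ± 0.33, the amino acid transporter Slc7a3 by 2.38 ± 0.26, Card6 by 2.23 ± 0.18 and Batf by 1.93 ± 0.24. Mx2 differed by -2.41 ± 0.37, Ifit3, an interferon-induced antiviral protein, by -3.24 ± 0.51, and S1pr3 by -1.66 ± 0.21. The mean signal of Mx2 with PL2-3 lay under the pseudocount, and its difference went from -1.55 with a pseudocount of 245 to -3.43 with none. For interferon-stimulated genes, 9 of 27 tested members were lower with PL2-3 and 18 were not called (20 lower adjusted over the list alone). Their median change was -1.32 (camera adjusted p = 3.35e-32, and 0.180 with an estimated correlation). Marginal zone markers gave 1 called member, S1pr3, of 9 (4 adjusted over the list alone). Their median was 0.02, their mean -0.33 and their test lower (camera adjusted p = 0.00394, and 0.240 with an estimated correlation). That median was -0.22, -0.24 and -0.18 without anti-IgM replicates 1, 2 and 3, and -0.08, 0.19 and -0.24 without PL2-3 replicates 1, 2 and 3. By limma, 97 genes differed, 46 higher and 51 lower, and the count was 163 in a fit without the anti-IgM+CpG arrays and 58 with the Enzo arrays only. The count was 35 to 55 with 1 array left out. The self-test recovered 86.4% of 4-fold, 29.9% of 2-fold and 7.46% of 1.5-fold simulated changes in this comparison.

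PL2-3 against CpG compares chromatin complexes with the TLR9 stimulus alone. Mx2 was lower with PL2-3, at a log2 difference of -4.09 ± 0.37 (n = 3 arrays per group), at a mean signal of 60.1 ± 11 against 2340.1 ± 956 (SD). Its PL2-3 signal lay under the pseudocount, and the difference went from -3.02 with a pseudocount of 245 to -5.22 with none. Ifit3 differed by -3.52 ± 0.51, Ifit2 by -3.06 ± 0.44, Cxcl10 by -3.43 ± 0.50 and Ebi3 by -3.12 ± 0.23. Xcl1 was higher with PL2-3 by 4.65 ± 0.32, Bex1 by 3.40 ± 0.34, Cst7 by 3.39 ± 0.20, Crabp2 by 2.95 ± 0.47 and Rgs16, a regulator of G protein signalling, by 2.90 ± 0.34. For interferon-stimulated genes, 19 of 27 tested members were lower with PL2-3 and 8 were not called (25 lower adjusted over the list alone). Interferon-stimulated genes had a median change of -1.72 (camera adjusted p = 2.79e-38, and 0.0367 with an estimated correlation). Markers of other cell types, 46 in all, had a median of 0.0437 in the same comparison. In cytokines and chemokines, Ccl5 (-1.87 ± 0.29) was lower, and 6 of 22 members were lower, 1 was higher and 15 were not called (8 and 1 adjusted over the list alone). Cytokines and chemokines had a median change of -0.29 (camera adjusted p = 6.86e-06, and 0.0114 with an estimated correlation), and of -0.48 and -0.46 without PL2-3 replicates 2 and 3. For NF-kB targets, 5 of 16 were lower and 11 not called (9 adjusted over the list alone), with Cd40 at -1.53 ± 0.28. NF-kB targets had a median change of -0.48 (camera adjusted p = 3.73e-09, and 0.0491 with an estimated correlation).

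Immediate early genes leaned the other way between PL2-3 and CpG. Egr2 was higher with PL2-3 by 2.67 ± 0.22 and Egr1 by 2.34 ± 0.21, and Jun differed by -2.37 ± 0.26. Of that list 6 of 20 members were higher, 1 was lower and 13 were not called (9 and 1 adjusted over the list alone). Immediate early genes had a median change of 0.53 (camera adjusted p = 4.20e-06, and 0.147 with an estimated correlation, or 0.00945 actin-based). In TLR signalling, Socs3 (-1.31 ± 0.21) and Tlr1 (-1.25 ± 0.19) were lower, with 5 of 23 members lower, 1 higher and 17 not called (8 and 1 adjusted over the list alone). TLR signalling genes had a median change of -0.18 (camera adjusted p = 5.53e-05, and 0.0123 with an estimated correlation), and of -0.09 without CpG replicate 2. The survival genes Pim2 (-2.41 ± 0.26) and Bcl2 (-2.26 ± 0.24) were lower with PL2-3, while Tnfrsf13c (1.58 ± 0.19), the receptor for BAFF, and S1pr3 (2.46 ± 0.21) were higher. The unfolded protein response was higher at a median of 0.39, with 1 of 18 members higher and 17 not called (3 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.00364, and 0.551 with an estimated correlation). By limma, 422 genes differed, 210 higher and 212 lower with PL2-3, and 10 of 25 lists were called, 4 of them with an estimated correlation. Leaving out 1 array gave 210 without CpG replicate 1, 241 without CpG replicate 3, and 249, 262 and 246 without PL2-3 replicates 1, 2 and 3. With the Enzo arrays only 280 genes were called, and higher genes were 49.8% of those called and 26.6% with arrays shifted to the same median.

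**Figure D3:**
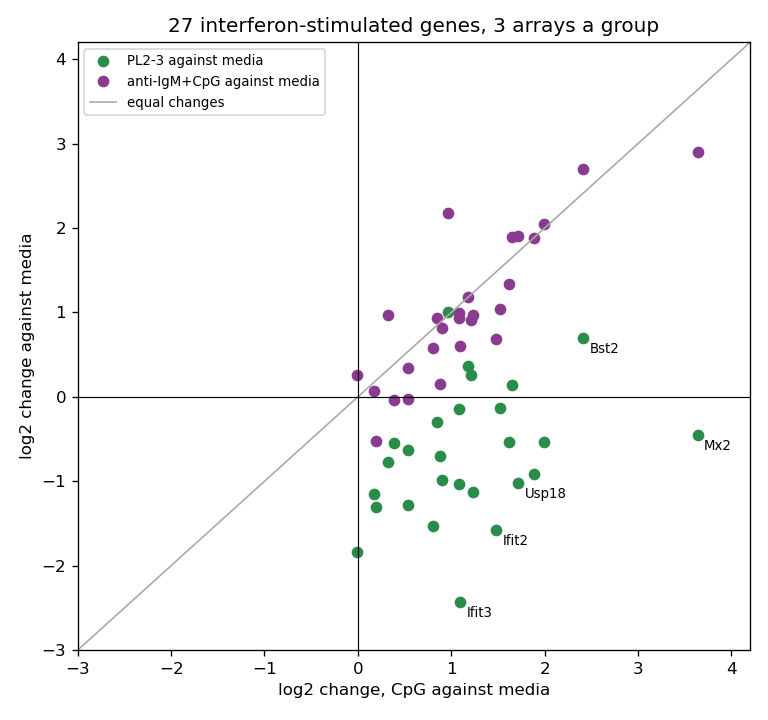
Log2 change against media of the 27 tested interferon-stimulated genes with CpG (horizontal axis) and with PL2-3 or with anti-IgM and CpG together (vertical axis), n = 3 arrays per group, with a line at equal changes. Mx2 was at 3.64 with CpG and -0.45 with PL2-3.

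PL2-3 against anti-IgM+CpG compares 1 ligand for both receptors with 2 separate ligands. Mx2 was lower with PL2-3, at a log2 difference of -3.35 ± 0.37 (actin-based -3.53 ± 0.40, n = 3 arrays per group), and so was Usp18, a regulator of interferon signalling, at -2.92 ± 0.48 (-3.21 ± 0.56). With PL2-3 the Mx2 signal lay under the pseudocount, and its difference went from -2.34 with a pseudocount of 245 to -4.44 with none. For interferon-stimulated genes, 15 of 27 tested members were lower with PL2-3 and 12 were not called (25 adjusted over the list alone). Interferon-stimulated genes had a median change of -1.75 and -1.91 actin-based (camera adjusted p = 3.95e-31, and 0.0990 with an estimated correlation, or 0.0207 actin-based). Xist, at 321 to 589 on the anti-IgM+CpG arrays, was higher with PL2-3 by 4.43 ± 0.34 (4.29 ± 0.38). Csf1r, a myeloid marker, was higher with PL2-3 by 2.31 ± 0.32 (1.63 ± 0.28). For the myeloid markers 5 of 20 were higher, 1 lower and 14 not called (6 and 1 adjusted over the list alone). Myeloid markers had a median change of 0.43 and 0.47 actin-based (camera adjusted p = 0.0104, and 0.600 with an estimated correlation). Their median was 0.71 without anti-IgM+CpG replicate 1, and their camera adjusted p was 0.109 without anti-IgM+CpG replicate 2 and 0.0543 without replicate 3. Of the NF-kB targets, 3 of 16 were lower with PL2-3 and 13 were not called (5 adjusted over the list alone). NF-kB targets had a median change of -0.35 and -0.48 actin-based (camera adjusted p = 1.73e-05, and 0.219 with an estimated correlation, or 0.0141 actin-based). Their median was -0.17 without anti-IgM+CpG replicate 3, and their camera adjusted p after quantile normalization was 0.0694. By limma, 234 genes differed, 166 higher and 68 lower, against 89 actin-based, 44 and 45, with 59 called the same way in both. Without anti-IgM+CpG replicate 3 the count was 1592, without replicate 2 of that group 71, and without PL2-3 replicates 1, 2 and 3 it was 46, 24 and 84. Higher genes were 70.9% of those called, 55.2% after quantile normalization and 8.40% with arrays shifted to the same median.

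Cytokine genes were higher with both agents than with anti-IgM, where CpG was not the only difference. Ifng was higher by 4.34 ± 0.76 log2 units (actin-based 5.74 ± 0.90, n = 3 arrays per group), Tbx21 by 3.61 ± 0.47 (3.80 ± 0.53) and Il6 by 3.43 ± 0.33 (3.97 ± 0.36). Socs3 was higher by 2.94 ± 0.21 (actin-based 3.43 ± 0.18), Batf by 2.74 ± 0.24 (2.80 ± 0.26), Slamf1, a signalling lymphocyte receptor, by 2.03 ± 0.29 (2.0 ± 0.31) and Cd40 by 1.46 ± 0.28 (1.33 ± 0.31). Ephx1, an epoxide hydrolase, differed by -3.27 ± 0.29 (actin-based -3.30 ± 0.32), Rgs2 by -2.84 ± 0.23 (-2.42 ± 0.24), Fcmr by -2.96 ± 0.26 (-3.26 ± 0.27) and the immediate early gene Egr3 by -2.42 ± 0.26 (-2.04 ± 0.29). For cytokines and chemokines, 8 of 22 tested members rose, 1 fell and 13 were not called (10 rose and 1 fell adjusted over the list alone). Cytokines and chemokines had a median change of 0.62 and 0.88 actin-based (camera adjusted p = 3.01e-05, and 0.0170 with an estimated correlation). For NF-kB targets, 8 of 16 tested members rose and 8 were not called (9 adjusted over the list alone). NF-kB targets had a median change of 0.64 and 0.70 actin-based (camera adjusted p = 2.20e-06, and 0.125 with an estimated correlation, or 0.0183 actin-based). Marginal zone markers were lower, with S1pr3 at -2.27 ± 0.21 (actin-based -2.24 ± 0.23). In this list, 5 of 9 tested members fell and 4 were not called (6 adjusted over the list alone). Marginal zone markers had a median change of -0.95 (camera adjusted p = 3.01e-05, and 0.0888 with an estimated correlation). Beside these, Xist differed by -4.51 ± 0.34 (actin-based -4.36 ± 0.38) and of the myeloid markers 4 of 20 tested members fell and 16 were not called (7 adjusted over the list alone). Myeloid markers had a median change of -0.60 (camera adjusted p = 0.00133, and 0.438 with an estimated correlation), and of -0.93 and -0.37 without anti-IgM+CpG replicates 1 and 2. By limma, 1178 genes differed, 488 higher and 690 lower, against 505 actin-based, 171 and 334, with 394 called the same way in both. The count was 588, 408 and 686 without anti-IgM replicates 1, 2 and 3, and 501 and 2072 without anti-IgM+CpG replicates 2 and 3. Higher genes were 41.4% of those called and 86.4% with arrays shifted to the same median.

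Both agents were also compared with CpG alone. Xcl1 was higher by 4.04 ± 0.32 log2 units (actin-based 4.27 ± 0.34, n = 3 arrays per group), Cst7 by 2.92 ± 0.20 (2.88 ± 0.21), and Egr2 by 2.50 ± 0.22 (2.60 ± 0.24) with its corepressor Nab2 by 1.67 ± 0.21 (1.82 ± 0.22). Ebi3 differed by -2.76 ± 0.23 (actin-based -2.80 ± 0.25), Fcer2a, which encodes CD23, by -2.76 ± 0.36 (-2.42 ± 0.37), Klf2 by -2.28 ± 0.33 (-1.83 ± 0.33), Pim2 by -2.48 ± 0.26 (-2.34 ± 0.29) and Bcl2 by -1.95 ± 0.24 (-2.08 ± 0.25). Tnfrsf13c was higher by 1.62 ± 0.19 (actin-based 1.63 ± 0.20) and S1pr3 by 1.84 ± 0.21 (1.87 ± 0.23). For cholesterol synthesis and uptake, 6 of 17 tested members rose and 11 were not called (8 adjusted over the list alone). Cholesterol genes had a median change of 0.52 and 0.33 actin-based (camera adjusted p = 2.47e-09, and 0.0859 with an estimated correlation). For glycolysis and lactate export, 1 of 14 tested members rose and 13 were not called (7 adjusted over the list alone). Glycolysis genes had a median change of 0.38 and 0.25 actin-based (camera adjusted p = 3.09e-05, and 0.163 with an estimated correlation). In the unfolded protein response, 3 of 18 tested members rose and 15 were not called (8 adjusted over the list alone). Unfolded protein response genes had a median change of 0.45 and 0.42 actin-based (camera adjusted p = 1.29e-05, and 0.424 with an estimated correlation), and of 0.22 without anti-IgM+CpG replicate 1. Beside these, Xist differed by -4.48 ± 0.34 (actin-based -4.34 ± 0.38). Of the myeloid markers 3 of 20 tested members fell and 17 were not called (6 adjusted over the list alone). Myeloid markers had a median change of -0.65 (camera adjusted p = 0.000324, and 0.427 with an estimated correlation), and of -0.15 without anti-IgM+CpG replicate 2. By limma, 570 genes differed, 245 higher and 325 lower, against 350 actin-based, 159 and 191, with 253 called the same way in both. Without CpG replicates 1 and 2 the count was 271 and 260, and without anti-IgM+CpG replicates 2 and 3 it was 275 and 1540. Higher genes were 43.0% of those called and 72.5% with arrays shifted to the same median.

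CpG against anti-IgM sets the TLR9 stimulus against the receptor stimulus. Il6 was higher with CpG by 4.94 ± 0.33 log2 units (n = 3 arrays per group), Ebi3 by 4.11 ± 0.23, Il12b by 2.98 ± 0.43 and Jun by 3.97 ± 0.26. Pim2 was higher by 2.89 ± 0.26, Bcl2 by 2.83 ± 0.24, Socs3 by 2.74 ± 0.21 and Batf by 2.63 ± 0.24. Lower with CpG were Xcl1 (-3.96 ± 0.32), Bex1 (-3.87 ± 0.34), S1pr3 (-4.11 ± 0.21), Ccr6 (-3.37 ± 0.33) and Egr3, at -3.86 ± 0.26 on its brightest probe set and -0.58 on another that passed the filter. Of the immediate early genes, 1 of 20 was higher with CpG, 11 were lower and 8 were not called (1 and 13 adjusted over the list alone). Immediate early genes had a median change of -0.90 (camera adjusted p = 1.81e-09, and 0.0878 with an estimated correlation, or 0.00377 actin-based). For NF-kB targets, 9 of 16 were higher, 1 was lower and 6 were not called (12 and 2 adjusted over the list alone), with Nfkbiz at 2.29 ± 0.20 and Bcl3 at 2.08 ± 0.21. NF-kB targets had a median change of 0.73 (camera adjusted p = 1.81e-09, and 0.0670 with an estimated correlation, or 0.0426 actin-based). Cytokines and chemokines had 8 of 22 higher, 1 lower and 13 not called (10 and 2 adjusted over the list alone, camera adjusted p = 1.08e-06, and 0.00640 with an estimated correlation). TLR signalling was called higher, with a median of -0.10, a mean of 0.35, and 8 of 23 members higher, 1 lower and 14 not called (8 and 1 adjusted over the list alone, camera adjusted p = 0.00674, and 0.0670 with an estimated correlation). That median was 0.11 and -0.02 without anti-IgM replicates 2 and 3, and 0.01 and 0.01 without CpG replicates 1 and 3. By limma, 844 genes differed, 340 higher and 504 lower with CpG. The count was 530 without anti-IgM replicate 3, 500 and 546 without CpG replicates 1 and 3, 539 with the Enzo arrays only and 520 with arrays shifted to the same median, where higher genes were 51.5% of those called against 40.3%.

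**Figure D4:**
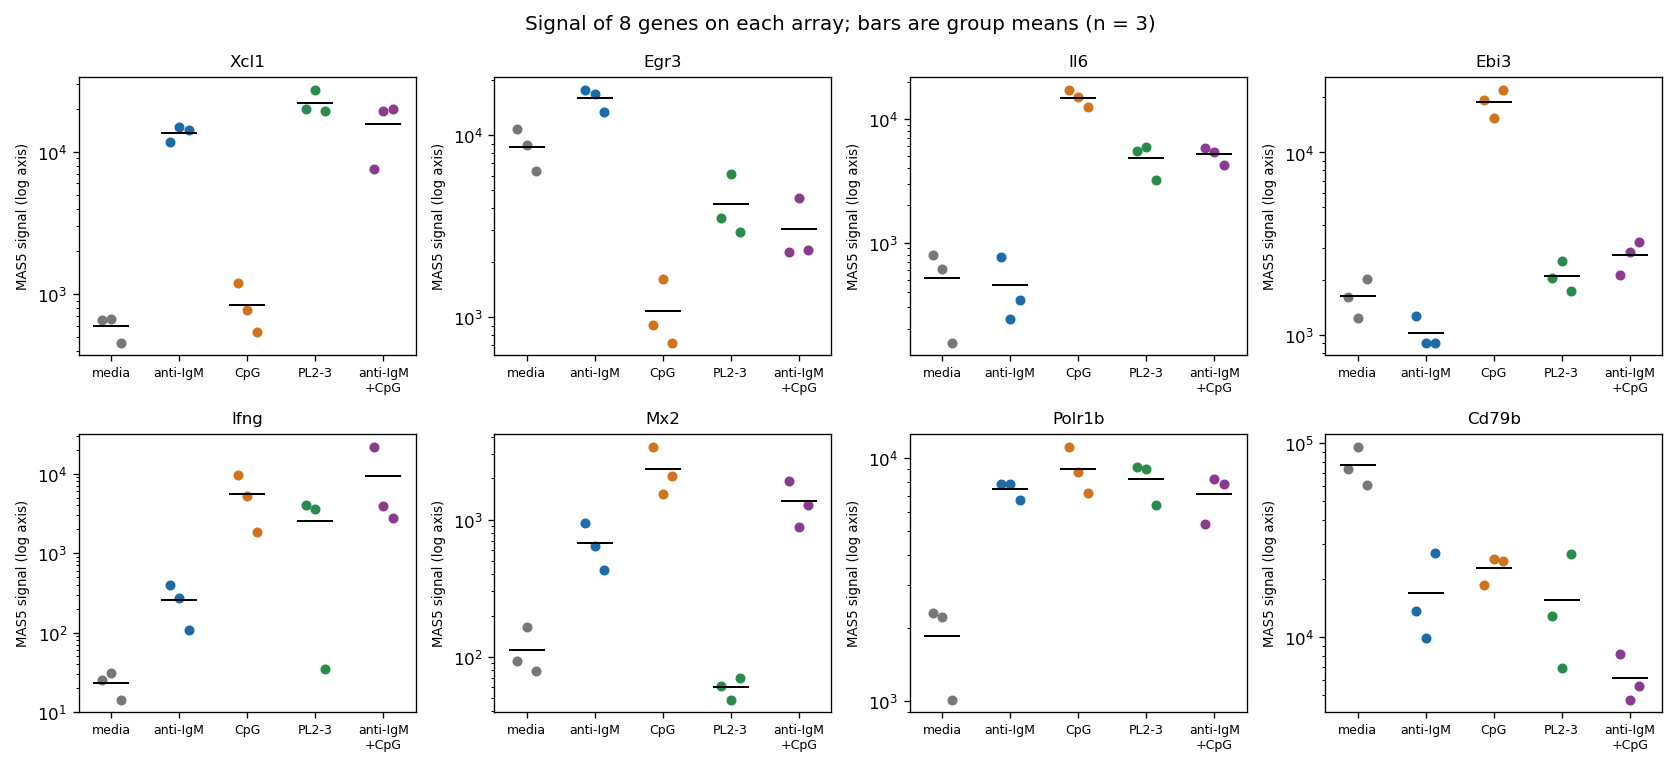
MAS5 signal (log axes) of 8 genes on each of the 15 arrays by group, with bars at the group means (n = 3). Xcl1 and Egr3 were higher with anti-IgM than with CpG, Il6 and Ebi3 were higher with CpG than with anti-IgM, and Ifng on PL2-3 replicate 3 was 34.6 against 3618 and 4076 on the other PL2-3 arrays.

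The non-additivity of anti-IgM and CpG asks whether the log2 change with both agents differed from the sum of the changes with each. Siglecg, an inhibitory lectin of B cells, was above the sum by 3.27 ± 0.34 log2 units (actin-based 2.97 ± 0.34, n = 3 arrays per group), Mical3 by 3.25 ± 0.50 (3.14 ± 0.52) and Pou2af1 by 2.47 ± 0.24 (2.38 ± 0.24). The mean signal of Mical3 with CpG lay under the pseudocount, and its value went from 2.24 with a pseudocount of 245 to 4.38 with none. Below it were Lmnb2 at -2.92 ± 0.34 (actin-based -3.11 ± 0.35), Polr1b at -2.39 ± 0.32 (-2.01 ± 0.29), Ebi3 at -2.15 ± 0.32 (-2.19 ± 0.33) and Xist at -5.07 ± 0.48 (-4.93 ± 0.51). Polr1b had risen by 2.05 with anti-IgM, 2.31 with CpG and 1.97 with both. In ribosome biogenesis, 13 of 23 tested members were below the sum and 10 were not called (20 adjusted over the list alone). Ribosome biogenesis genes had a median change of -1.05 and -1.09 actin-based (camera adjusted p = 8.62e-20, and 0.142 with an estimated correlation). Interferon-stimulated genes were below it at a median of -0.78, -0.63 actin-based, with 1 of 27 called lower and 26 not called (5 adjusted over the list alone, camera adjusted p = 1.76e-05, and 0.528 with an estimated correlation), and their median was -1.17 without anti-IgM+CpG replicate 1. The quiescence list lay above the sum at a median of 0.56, 0.47 actin-based, with 3 of 20 called higher and 17 not called (7 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.00214, and 0.194 with an estimated correlation). Mitosis genes lay above it too, at 1.28 (camera adjusted p = 1.76e-05, and 0.528 with an estimated correlation), and at 0.68 without media replicate 3 and 0.63 without anti-IgM+CpG replicate 1. So did erythroid markers, at 1.01 (camera adjusted p = 0.0204, and 0.528 with an estimated correlation), a call that ended without media replicate 3 (0.151), anti-IgM replicate 3 (0.0597), CpG replicate 3 (0.0779) or anti-IgM+CpG replicate 1 (0.0991). Actin-based, NK cell and T cell markers were called as well, at 1.17 and 0.61 (camera adjusted p = 0.000710 and 0.0386, against 0.0596 and 0.214 with the kits as labelled), but with an estimated correlation neither was, at 0.434 for both (0.603 with the kits as labelled). No member of these 4 lists was called. By limma, 333 genes were called, 112 above and 221 below the sum, against 337 actin-based, with 215 called the same way in both. Leaving out 1 array gave 142 without media replicate 3, 92, 187 and 84 without anti-IgM replicates 1, 2 and 3, 77, 191 and 83 without CpG replicates 1, 2 and 3, and 201, 219 and 1281 without anti-IgM+CpG replicates 1, 2 and 3. From only the 7 arrays with the Ambion pattern limma called 0 genes, with 1922 at an unadjusted p under 0.05.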

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

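The tests of the 3 patterns weighed here were all chosen after the results were seen, and the counts of other splits of the arrays were chosen before.

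The test of the difference itself, whether the change with both agents departs from the sum of the changes with each, singled out 333 genes by limma. Among the genes it named, Siglecg (3.27), Mical3 (3.25) and Pou2af1 (2.47) were above the sum on the log2 scale. The size for Mical3 depends on the pseudocount, since its mean signal with CpG lay under it. Xist (-5.07), Lmnb2 (-2.92), Polr1b (-2.39) and Ebi3 (-2.15) were below it. Of 100 splits of the 12 arrays drawn at random, the real one included, 3 called as many genes, a share under 0.05. The splits mix treatments within a group, which widens the spread, and the median of the others was 0 genes, so this share does not by itself exclude chance. The highest of the others called 2289, several times the real count. It placed the 3 media arrays together as if they were the anti-IgM group, which points to the structure of the samples, media against stimulated.

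For each comparison of 3 arrays with 3, only the real split, 1 of 10, called as many genes, and 10 splits are too few for a share under 0.05. The real counts were 2561 for anti-IgM, 3975 for CpG, 3426 for PL2-3 and 5491 for anti-IgM+CpG against media. They were 97, 422 and 234 for PL2-3 against anti-IgM, CpG and the combination, 1178 and 570 for the combination against anti-IgM and CpG, and 844 for CpG against anti-IgM. The highest other split called 1 gene for anti-IgM+CpG against media and 0 for each of the other 9 comparisons.

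The anti-IgM+CpG arrays stood apart from the other 12, and Xist differed from the mean of the other groups by -4.33 log2 units. Across genes, replicates 1 and 2 minus replicate 3 had a slope of -0.0147 on the labelling effect of the other groups, against 0.452 to 0.953 within those groups, so a candidate explanation is that all 3 were labelled with 1 kit. Another mix of female and male mice cannot be told apart from the other causes. The first test, the median of all 6 Y-linked genes, was -0.104. Eif2s3y and Kdm5d, the 2 expressed outside the testis, had a mean of 0.836, chosen after that result, against -0.40 to -0.08 for the others. On media replicate 3 the signals of both genes lay above all 3 anti-IgM+CpG arrays, and Xist was the lowest of the other 12. Stimulation with both agents also stays open, since the 3 arrays hold all of that group, and the Xist change of 0.52 with PL2-3 against media does not decide it.

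Interferon-stimulated genes were lower with PL2-3 than with CpG, with a list median of -1.72. Transcripts from T, myeloid, NK and erythroid cells were argued against by a median of 0.0437 (95% bootstrap interval -0.137 to 0.249) over 46 markers. The scaling and the labelling were argued against by a median of -1.67 under the alternative with the smallest fall, the Enzo arrays only, and a single array by -1.55 without CpG replicate 1. A difference between the stimuli is a hypothesis these values leave standing. Other cell types stay open too, as do dose and time, which the labels do not give.

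Ribosome biogenesis genes were lower with both agents than the sum of the changes with each, with a list median of -1.05. The median was -1.09 with actin-based labelling and -1.05 under the scaling with the smaller fall, which argues against either as the whole cause. With PL2-3 in place of anti-IgM+CpG the median was -1.44 (camera adjusted p = 5.96e-25, and adjusted p = 0.0664 with an estimated correlation), but PL2-3 is another stimulus and shares the media, anti-IgM and CpG arrays, so this value does not measure the preparation of the anti-IgM+CpG cells. That preparation cannot be told apart from stimulation with both agents, and a ceiling on how far these genes can rise may give the same result, which was not tested.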

How the results depend on the processing

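The actin-based labelling term, the fit without the anti-IgM+CpG arrays, the 7 Ambion-like arrays, and the gene lists with arrays shifted to the same median or 1 array left out were chosen after the data were seen, and the other alternatives were planned. Where the alternative does not itself show the cause (fewer arrays, a stricter threshold), the cause was not tested.

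With the Enzo arrays only, 2 per group, 1438 genes were called for anti-IgM and 2481 for CpG against media. CpG against anti-IgM gave 539, and PL2-3 against anti-IgM and CpG 58 and 280. PL2-3 against both gave 1278 and both against anti-IgM and CpG 1783 and 1270, where kit and group coincide by actin ratio. With at least a 2-fold change the counts against media were 1151, 2032, 1711 and 3139 for anti-IgM, CpG, PL2-3 and both, 574 and 340 for both against anti-IgM and CpG, and 518 for CpG against anti-IgM. Arrays shifted to the same median gave 63 for PL2-3 against anti-IgM, 1250 for PL2-3 against both, 520 for CpG against anti-IgM and 30 for non-additivity. Quantile normalization gave 87 for PL2-3 against both, 698 for both against anti-IgM and 779 for non-additivity.

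For PL2-3 against anti-IgM, CpG and both, both against anti-IgM and CpG, and non-additivity, in that order, the counts were 50, 256, 27, 358, 222 and 56 without a labelling term, 33, 267, 72, 680, 332 and 24 with eBayes without a trend, and 218, 646, 24, 302, 202 and 146 in fits of the compared groups only. PL2-3 against anti-IgM gave 62 with the mean of the probe sets and 163 without the anti-IgM+CpG arrays. Actin-based labelling gave 89 for PL2-3 against both and 505 and 350 for both against anti-IgM and CpG. The 7 Ambion-like arrays, with 2 residual degrees of freedom, gave 2284 genes by limma for both against media (4601 at an unadjusted p under 0.05), 0 for PL2-3 against both (779), 9 and 22 for both against anti-IgM and CpG (1085 and 798), and 0 for non-additivity (1922). In that fit the groups with 1 array are assumed to vary like the group with 3. Every other planned count was within 1.5 times the one reported.

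Leaving out 1 array gave 1654 to 2178 genes for anti-IgM, 2864 to 3477 for CpG, 2480 to 2964 for PL2-3 and 4332 to 5378 for both against media. The ranges were 35 to 55 for PL2-3 against anti-IgM, 210 to 323 against CpG and 24 to 1592 against both, 408 to 2072 for both against anti-IgM and 260 to 1540 against CpG, 500 to 707 for CpG against anti-IgM and 77 to 1281 for non-additivity. Each gene count involving anti-IgM+CpG was highest without its replicate 3, leaving arrays given as Enzo with Ambion-like actin ratios. Gene lists called were 126 to 146.

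With a replicate block, a pairing not seen for anti-IgM+CpG, counts against media were 2605, 3993, 3470 and 5508 for anti-IgM, CpG, PL2-3 and both. They were 104, 440 and 273 for PL2-3 against anti-IgM, CpG and both, and 1206 and 590 for both against anti-IgM and CpG. CpG against anti-IgM gave 873 and non-additivity 340.

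Of 275 tests of lists, 132 were called, and 12 with an estimated correlation, which became 30 with actin-based labelling, 11 of them called in both. Of the 132, the call was kept in the same direction in 115 with quantile normalization, 125 with arrays shifted to the same median, 130 with the replicate block, 128 without a labelling term, 114 with the Enzo arrays only, 131 without the filter and 120 with actin-based labelling. The list of cholesterol synthesis and uptake reversed for PL2-3 against both with actin-based labelling, to 0.060 (camera adjusted p = 0.834). Correlations of the changes with Enzo arrays only fell to 0.655 for anti-IgM and both and 0.667 for PL2-3 and both.

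The 234 values of named genes, picked as called, kept direction and call in each alternative run, except some on the 7 Ambion-like arrays. This says nothing of other genes. With the mean of the probe sets, values against media moved by over 1.5 times for Ahr (1.74), Arhgef18 (-1.74), Nr4a2 (1.09) and Bcl2 (-0.73) with anti-IgM, Lmnb2 (2.38), Egr3 (-1.56) and Nr4a2 (-1.06) with CpG, Mxd4 (-2.40), Arhgef18 (-2.05) and Cenpa (-1.21) with PL2-3, and Nfkbiz (1.29) and Bcl2l11 (-1.47) with both. Against anti-IgM, Egr3 moved to -1.54 with both and -2.22 with CpG. Nr4a3 with anti-IgM was 1.48 on the Enzo arrays, Rnd3 with CpG 2.19 without a pseudocount, Mx2 in PL2-3 against anti-IgM -1.55 with a pseudocount of 245, and Bcl2l11 and C1qa with both -1.05 and -2.32 with actin-based labelling. Genes with signals near the background were left out by the filter, and changes among them were not measured.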

Other observations

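The tests in this part were planned, and the genes were picked from the named members of the lists after their values were seen. Of the genes called against media with both single agents, 61 went in opposite directions with anti-IgM and CpG. S1pr3, a sphingosine receptor, rose by 1.86 ± 0.21 log2 units with anti-IgM and changed by -2.25 ± 0.21 with CpG (n = 3 arrays per group). Its values were 0.21 ± 0.21 with PL2-3 and -0.41 ± 0.21 with both agents, neither of them called by limma. The survival gene Bcl2 went the other way, at -1.34 ± 0.24 with anti-IgM, or -0.73 with the mean of its probe sets, and 1.49 ± 0.24 with CpG. Against each other, CpG minus anti-IgM, the limma differences were -4.11 ± 0.21 for S1pr3 and 2.83 ± 0.24 for Bcl2.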
